A study of Homo sapiens with 6 samples.

How the data were processed

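Gene expression was measured by RNA sequencing in 6 libraries of H9 human embryonic stem cells taken at 6 time points, from day 0 to day 30, of cardiac organoid differentiation. Per the labels' protocols, messenger RNA was purified with poly-T beads, fragmented and reverse transcribed from random hexamers. Tools named in the submitters' processing notes are CASAVA, HISAT2 and featureCounts 1.5.0-p3, and their settings are not given in the sources used here, nor is the genome build or whether counting used strand. The authors deposited 1 table of FPKM values, a read count scaled by gene length and by a library denominator, for 58735 genes and 6 libraries, with each gene's position, length and class. All 58735 gene identifiers, starts, ends and strands equal those of GENCODE release 29 (Ensembl release 94) on GRCh38. Each column name held the day of 1 sample's title, so every column was matched. It is therefore not known whether reads of overlapping and antisense genes were separated, and reads of near-identical genes, such as CFC1 and CFC1B, metallothioneins, or MYH6 and MYH7, may have been split or lost.

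The product of FPKM and gene length was a whole multiple of 1 step in each library, within 0.001 read for 100% of the values above 0, so whole reads were recovered. Totals of recovered reads lay between 13500887 and 15526924. The denominators behind the deposited FPKM differed from these totals, at 0.826 times the total for day 30 and 1.12 times for day 6, and stood between 0.992 and 1.01 times those of a median-of-ratios scaling of the reads. The deposited values thus carry a scaling between libraries that differs from read totals by most at day 30. For a gene of 1 kilobase, 1 read equals 0.0578 FPKM at day 6 and 0.0809 FPKM at day 30.

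Choices below were made before the data were examined unless said otherwise. Differences were taken on log2(FPKM + 1), with a pseudocount of 1, which understates the change of low genes. A gene entered a comparison with an FPKM of at least 1 in at least 1 of the 2 libraries, and was called higher or lower at a difference of at least 1. The 5 consecutive steps and day 30 against day 0 were compared. With 1 library per time point there was no test across samples and no p-value. Folds are ratios of FPKM with exact conditional binomial 95% intervals from the recovered reads, and levels and shares have exact Poisson and Clopper-Pearson intervals. All of these cover counting error only and not variation between samples, since each day had 1 library. Reads were not molecules counted by identifiers, so copies of 1 molecule may count as separate reads. The intervals may therefore be too narrow even for counting error. The intervals of folds also leave out the choice of scaling between libraries. Where 1 library had 0 reads, the fold is a lower bound against a floor of 3 reads in that library.

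Named genes are the 10 protein-coding genes with the greatest rise and the 10 with the greatest fall in each comparison, the 2 to 4 members with the largest and smallest change of each of 43 gene lists fixed in advance and members that go against their list, and the genes of 3 paired shares. A few genes outside this rule were chosen after their values were seen, namely SOX2 and POU5F1 at day 2, MESP1 at day 3, MSX1 at day 4, TPM1 at day 6, MKI67 at day 30 against day 6, TNNT2, ACTN2 and TBX20 at day 30 against day 0, and further genes in the closing observations. For each list the median difference was placed among 10000 random lists of the same size drawn from 10 bins of mean expression, and lists with under 3 measured genes received no percentile. Some genes belong to more than 1 list. Results of a few genes that the rule names are not reported here. The day of highest expression was counted for genes past the rule between their lowest and highest day.

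The procedure was tested on simulated reads, with 200 genes of the table changed by known folds. For day 2 against day 0, 87% of the 3-fold and 99% of the 8-fold changes were called, and for day 30 against day 0, 85% and 100%. Counting noise alone called 248 unchanged genes of 15323 tested in the first and 362 of 16548 in the second. For day 4 against day 3 it called 299 of 15925, where only 1281 genes were called in the data. Of 200 simulated lists without a change, 6.5% fell outside the percentiles for day 2 against day 0 and 8% for day 30 against day 0. In the simulation 200 genes were changed and the others differed by counting noise alone. In the data 2648 and 8041 genes were called in these comparisons, and members of a list can change together. The simulated shares therefore do not give the rate of false calls among the lists reported below.

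Alternatives were a pseudocount of 0.1, no minimum and a minimum FPKM of 5, 3 other scalings between libraries, protein-coding genes only, a rule of 2, a counting interval that excludes 1, list means, members of 1 list only, read shares without gene length, and leaving out day 30. Scaling by recovered read totals and the subtraction of medians over 20 bins of transcript GC content were added after seeing the data. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.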

Results

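RNA was measured in 6 libraries of the H9 line, an established human embryonic stem cell line, during differentiation into cardiac organoids, which are small 3-dimensional cultures of heart cell types. The libraries stand for 6 time points from day 0 to day 30, with 1 library for each, and 10 organoids were harvested per time point, per the labels. Recovered reads were 14824424 at day 0, 15526924 at day 2 and 13500887 at day 3. Day 4 had 14890104, day 6 had 15418010 and day 30 had 14962790. Genes with an FPKM of at least 1 numbered 14357 at day 0 and 15457 at day 30. With 1 library per day no difference has a replicate check, so no p-value is given. A gene is called higher or lower when its log2(FPKM + 1) differs by at least 1 and its FPKM is at least 1 in either library. Folds are given with 95% intervals, which cover counting error only and not the choice of scaling between libraries. For each list the parentheses give the measured members that were higher and lower, the median log2 difference, and its percentile among 10000 random lists matched on expression. Members under an FPKM of 1 in both libraries are left out. A gene silent on 1 day is thus measured only if it is expressed on the other, and these fractions do not describe whole lists. A list is called above or below other genes when that percentile lies in the outer 5%, as a description of these libraries. Gene positions are those of the deposited table, which equal GRCh38 coordinates of GENCODE.

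The comparison of day 2 with day 0 asks which genes changed in the first step out of the embryonic stem cell state. Genes of the primitive streak, the structure through which mesoderm and endoderm form, rose. TBXT (ENSG00000164458, chromosome 6, 166157656 to 166168700, minus strand), a T-box factor of the streak, was at least 2015-fold higher and had 158 FPKM at day 2. The homeobox factor MIXL1 (0.509 to 472 FPKM, 927-fold higher, 562 to 1656) and the T-box factor EOMES (0.0377 to 167 FPKM, 4432-fold higher, 1227 to 36604) rose with it. The primitive streak (13 of 13 higher, 0 lower, median 5.78, percentile 100) list was above other genes. Among pluripotency genes, TERF1 (101 to 9.04 FPKM, 11.1-fold lower, 10.5 to 11.8), which encodes a telomere-binding protein, and SOX2 (74.7 to 19.6 FPKM) fell. POU5F1, the central pluripotency factor, stood at 561 and 352 FPKM and did not pass the rule.

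Among the 10 protein-coding genes with the greatest rise were the WNT antagonists DKK4 (0 to 597 FPKM, at least 2583-fold higher) and DKK1 (0.0624 to 211 FPKM, 3379.7-fold higher, 935 to 27912). The NODAL and BMP antagonist CER1 (0.963 to 408 FPKM) and the growth factor FGF17 (0.272 to 153 FPKM) were also among them. The apelin receptor APLNR (0.110 to 358 FPKM, 3237-fold higher, 1487 to 8823) and the transcription factors SP5 (2.21 to 340.4 FPKM) and LHX1 (0.296 to 116 FPKM) complete the 10 with the streak factors. Of the 10 with the greatest fall, 4 were metallothioneins, metal-binding proteins of similar sequence whose reads can be shared. These were MT1G (67.9 to 1.74 FPKM, 39.1-fold lower, 25.4 to 63.5), MT1E (14.9 to 0.0590 FPKM), MT1H (15.2 to 0.258 FPKM) and MT2A (23.6 to 1.05 FPKM). TERF1, TRIML2 (24.98 to 0.753 FPKM), the RNA polymerase III subunit POLR3G (63.8 to 4.99 FPKM) and HES3 (40.8 to 2.94 FPKM) were others. The tryptophan-degrading enzyme IDO1 (10.6 to 0.190 FPKM) and ZDHHC22 (26.1 to 1.70 FPKM) fell as well.

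The early and cardiac mesoderm (15 of 16 higher, 1 lower, median 3.08, percentile 100) list was above other genes. Its member MSGN1 (0 to 40.6 FPKM) rose, and the growth factor receptor KDR (83.4 to 37.5 FPKM) went the other way. The WNT targets (10 of 12 higher, 0 lower, median 3.04, percentile 100) and BMP targets (8 of 9 higher, 0 lower, median 1.71, percentile 100) lists were above other genes. The NODAL targets (3 of 6 higher, 0 lower, median 0.998, percentile 99.77) list was above other genes. Examples were AXIN2 (4.03 to 19.7 FPKM), MSX1 (0.130 to 96.9 FPKM) and NODAL (1.95 to 49.3 FPKM). The cardiac transcription factors (4 of 7 higher, 0 lower, median 2.52, percentile 100) list was above other genes. Its members GATA6 (0 to 65.4 FPKM), GATA4 (0.0465 to 16.2 FPKM), TBX3 (0.0694 to 27.3 FPKM) and HAND1 (0.436 to 7.25 FPKM) rose. The mesenchymal (6 of 8 higher, 0 lower, median 1.31, percentile 100) list was above other genes. The cadherin CDH2 (7.44 to 96.6 FPKM) and the zinc finger factor SNAI1 (8.82 to 77.8 FPKM) belong to it. The epithelial (0 of 10 higher, 3 lower, median -0.78, percentile 0.02) and pluripotency (0 of 20 higher, 11 lower, median -1.17, percentile 0) lists were below other genes. The splicing regulator ESRP1 (63.5 to 26.7 FPKM) of the epithelial list and PRDM14 (31.05 to 3.28 FPKM) of the pluripotency list fell.

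The immediate early (5 of 9 higher, 0 lower, median 1.06, percentile 100) and retinoic acid and HOX (4 of 5 higher, 1 lower, median 1.47, percentile 99.86) lists were above other genes. The second heart field (3 of 4 higher, 0 lower, median 1.39, percentile 99.64) and epicardial (3 of 3 higher, 0 lower, median 1.45, percentile 99.03) lists were above other genes. The full epicardial list holds 12 genes, and without the FPKM minimum its median was 0 at percentile 50.27. The endothelial and endocardial (4 of 8 higher, 3 lower, median 1.06, percentile 99.94) and fibroblast and matrix (4 of 10 higher, 1 lower, median 0.65, percentile 99.83) lists were above other genes. The glycolysis (0 of 17 higher, 0 lower, median -0.40, percentile 1.465) and hypoxia (1 of 10 higher, 4 lower, median -0.69, percentile 0.12) lists were below other genes. The mitochondrial genome (0 of 13 higher, 1 lower, median -0.39, percentile 3.04) and cell cycle (0 of 22 higher, 0 lower, median 0.08, percentile 77.35) lists were not called.

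In total 1406 of 16019 genes were higher at day 2 and 1242 lower, and the interval of the fold excluded 1 for 1143 and 1014 of them. The endothelial, epicardial, matrix and glycolysis calls were lost under at least 1 alternative setting, and the counts became 3625 and 2781 under TPM scaling, 2130 and 2092 with a pseudocount of 0.1, 698 and 621 at an FPKM minimum of 5, and 1106 and 1183 with GC bins subtracted, a setting chosen after seeing the data.

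**Figure D1:**
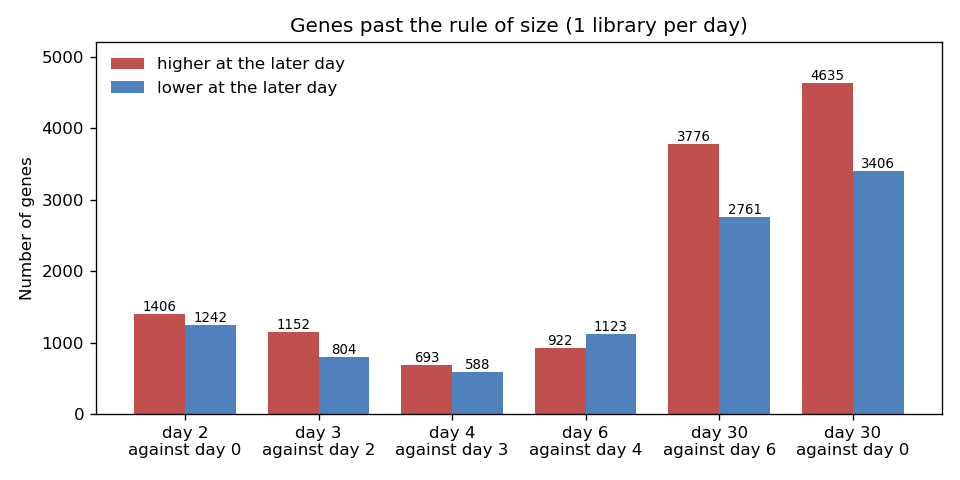
Bars give the number of genes (vertical axis) that were higher or lower at the later day in each of the 6 comparisons, with 1 library per day. The 2 comparisons with day 30 hold the most, with 3776 higher against day 6 and 4635 higher against day 0.

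Between day 2 and day 3, 7 of 13 primitive streak genes fell and 6 of 16 mesoderm genes rose. TBXT (158 to 10.4 FPKM, 15.2-fold lower, 13.7 to 16.9) and the growth factor NODAL (49.3 to 2.64 FPKM, 18.7-fold lower, 14.6 to 24.4) fell. MESP2 (ENSG00000188095, chromosome 15, 89760591 to 89778754, plus strand), a basic helix-loop-helix factor of early mesoderm, rose from 4.84 to 52.9 FPKM (10.9-fold higher, 9.17 to 13.1). HAND1 (7.25 to 121 FPKM, 16.6-fold higher, 14.4 to 19.3), a factor of heart and extraembryonic mesoderm, rose with it, and MESP1 (25.2 to 65.2 FPKM) reached the highest of its 6 levels. The primitive streak (0 of 13 higher, 7 lower, median -1.39, percentile 0) list was below other genes. The early and cardiac mesoderm (6 of 16 higher, 2 lower, median 0.62, percentile 100) list was above other genes.

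The greatest rise belonged to CFC1 (0.335 to 40.6 FPKM, 121-fold higher, 63.7 to 266), a NODAL co-receptor whose reads cannot be separated with certainty from its near-identical copy CFC1B. The serine protease HTRA1 (4.85 to 70.4 FPKM), the WNT antagonist SFRP5 (0.271 to 13.9 FPKM), SEMA3G (1.43 to 26.1 FPKM) and DLK1 (1.08 to 21.9 FPKM) followed. The iron exporter SLC40A1 (0.344 to 12.9 FPKM), GATA3 (0.777 to 15.2 FPKM) and the BMP-binding protein BMPER (1.67 to 22.8 FPKM) rose too. The greatest fall was that of DKK4 (597 to 10.7 FPKM, 55.8-fold lower, 47.2 to 66.6). The immediate early factors EGR1 (112 to 4.27 FPKM, 26.2-fold lower, 22.7 to 30.4) and FOS (42.9 to 2.24 FPKM) were also among the 10 greatest falls. MSGN1 (40.6 to 2.30 FPKM), CDX1 (20.6 to 1.63 FPKM) and the growth factor FGF4 (33.4 to 3.73 FPKM) also fell. So did GBX2 (6.84 to 0.120 FPKM) and the prohormone convertase PCSK1 (10.5 to 0.723 FPKM).

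The immediate early (0 of 9 higher, 6 lower, median -1.60, percentile 0) and WNT targets (1 of 12 higher, 6 lower, median -0.95, percentile 0) lists were below other genes. The NODAL targets (1 of 6 higher, 4 lower, median -1.52, percentile 0) and pluripotency (0 of 20 higher, 7 lower, median -0.70, percentile 0) lists were below other genes. The NODAL antagonist LEFTY2 (0.441 to 6.56 FPKM) rose against its list. The mitochondrial genome (0 of 13 higher, 12 lower, median -1.20, percentile 0) and cell cycle (0 of 22 higher, 3 lower, median -0.62, percentile 0) lists were below other genes. All mitochondrially encoded genes together took 5.93% of reads at day 2 and 2.92% at day 3. The endoderm and liver (5 of 7 higher, 0 lower, median 1.26, percentile 100) and cardiac transcription factors (4 of 9 higher, 0 lower, median 0.67, percentile 99.68) lists were above other genes. The endoderm factor SOX17 (79.4 to 191 FPKM) rose. The fibroblast and matrix (5 of 10 higher, 1 lower, median 0.84, percentile 100) and hypoxia (3 of 11 higher, 1 lower, median 0.79, percentile 99.99) lists were above other genes. The glycolysis (2 of 17 higher, 0 lower, median 0.50, percentile 99.99) list was above other genes. Fibronectin FN1 (49.1 to 331 FPKM), NDRG1 (3.41 to 24.6 FPKM) and hexokinase HK2 (43.5 to 111 FPKM) are examples of these. The sarcomere (2 of 9 higher, 0 lower, median 0.52, percentile 97.67) and atrial (2 of 4 higher, 0 lower, median 1.01, percentile 99.09) lists were above other genes. The endothelial and endocardial (4 of 8 higher, 0 lower, median 0.82, percentile 99.96) and epicardial (2 of 3 higher, 1 lower, median 1.86, percentile 99.95) lists were above other genes. The neuroectoderm and neuron (2 of 4 higher, 0 lower, median 0.88, percentile 99.45) and cartilage (2 of 4 higher, 0 lower, median 0.94, percentile 99.63) lists were above other genes. The replication-dependent histone (2 of 3 higher, 0 lower, median 1.15, percentile 98.5) list was above other genes, and its full list holds 9 genes.

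Between these libraries 1152 of 16149 genes were higher at day 3 and 804 lower, against 4143 and 1959 under TPM scaling, 2061 and 1378 with a pseudocount of 0.1 and 572 and 367 at an FPKM minimum of 5. The neuroectoderm median changed sign without the FPKM minimum and under TPM scaling, and the sarcomere, atrial, endothelial, epicardial, cartilage and histone calls were lost under at least 1 alternative.

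Day 4 against day 3 was the step with the fewest changed genes, and cardiac transcription factors were among its greatest rises. NKX2-5 (ENSG00000183072, chromosome 5, 173232109 to 173235357, minus strand), a homeobox factor of heart progenitors, rose from 0.533 to 9.31 FPKM (17.5-fold higher, 10.6 to 30.95). ISL1 (3.41 to 26.5 FPKM, 7.77-fold higher, 6.52 to 9.32), a factor of the second heart field, and HAND2 (1.24 to 10.5 FPKM, 8.48-fold higher, 6.55 to 11.2) rose in the same step. The WNT ligand WNT8A (66.5 to 2.82 FPKM, 23.6-fold lower, 19.2 to 29.4) and the secreted antagonist CER1 (156 to 10.0 FPKM, 15.6-fold lower, 13.4 to 18.1) fell. The cardiac transcription factors (4 of 11 higher, 0 lower, median 0.48, percentile 99.97) and second heart field (2 of 6 higher, 0 lower, median 0.85, percentile 99.99) lists were above other genes.

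Other great rises were those of NKX2-6 (0.0770 to 5.45 FPKM), the paired-box factor PAX8 (0.999 to 14.9 FPKM), the cystatin CST1 (84.3 to 631 FPKM) and the mesenchymal homeobox factor PRRX1 (0.380 to 8.79 FPKM). The hormone precursor TRH (4.16 to 26.1 FPKM), ATP8B4 (0.180 to 4.79 FPKM) and ISM1 (2.20 to 14.7 FPKM) complete the 10. The collagen-crosslinking enzyme LOX (29.8 to 2.64 FPKM), NTS (58.0 to 6.23 FPKM), LZTS1 (50.5 to 7.44 FPKM) and LGALS12 (13.7 to 1.48 FPKM) fell. The greatest falls also took in DKK4 (10.7 to 1.06 FPKM), PSKH2 (20.1 to 3.05 FPKM), LEFTY2 (6.56 to 0.503 FPKM) and CA3 (5.79 to 0.438 FPKM).

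The BMP targets (5 of 9 higher, 0 lower, median 1.11, percentile 100) and NOTCH targets (2 of 6 higher, 0 lower, median 0.37, percentile 99.01) lists were above other genes. The BMP targets SMAD6 (17.0 to 46.7 FPKM) and MSX1 (96.9 to 210.1 FPKM) rose. The NODAL targets (0 of 4 higher, 4 lower, median -1.83, percentile 0) and glycolysis (0 of 17 higher, 6 lower, median -0.88, percentile 0) lists were below other genes. The hypoxia (0 of 10 higher, 4 lower, median -0.86, percentile 0) list was below other genes. The glucose transporter SLC2A1 (402 to 188 FPKM) and the glycolytic kinase PGK1 (402 to 154 FPKM) fell. The mitochondrial genome (3 of 13 higher, 0 lower, median 0.83, percentile 100) and retinoic acid and HOX (2 of 7 higher, 0 lower, median 0.71, percentile 99.56) lists were above other genes. The first heart field (1 of 3 higher, 0 lower, median 0.68, percentile 98.43) and unfolded protein response (1 of 10 higher, 0 lower, median 0.44, percentile 99.97) lists were above other genes. The sarcomere (3 of 11 higher, 0 lower, median 0.40, percentile 99.05) and atrial (3 of 5 higher, 0 lower, median 1.02, percentile 99.92) lists were above other genes. The endothelial and endocardial (3 of 11 higher, 0 lower, median 0.81, percentile 99.99) and epicardial (2 of 4 higher, 0 lower, median 0.96, percentile 99.64) lists were above other genes. The smooth muscle and pericyte (1 of 7 higher, 0 lower, median 0.37, percentile 98.64) list was above other genes. The primitive streak (1 of 13 higher, 5 lower, median -0.92, percentile 0) and early and cardiac mesoderm (1 of 16 higher, 5 lower, median -0.27, percentile 0.58) lists were below other genes. The pluripotency (0 of 20 higher, 6 lower, median -0.58, percentile 0) and cell cycle (0 of 22 higher, 1 lower, median -0.39, percentile 0) lists were below other genes. The neuroectoderm and neuron (0 of 4 higher, 1 lower, median -0.93, percentile 0.15) and neural crest (0 of 4 higher, 2 lower, median -0.92, percentile 0.13) lists were below other genes. The cartilage (0 of 4 higher, 1 lower, median -0.50, percentile 2.35) list was below other genes.

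Of 16376 genes, 693 were higher at day 4 and 588 lower, and the interval of the fold excluded 1 for 403 and 366. The ATP8B4 call and the calls of the first heart field, cardiac transcription factor, sarcomere, epicardial, smooth muscle, neuroectoderm and cartilage lists were lost under at least 1 alternative, and the counts turned to 209 higher and 233 lower at an FPKM minimum of 5 and to 2240 and 2369 under TPM scaling, and were 1260 and 1101 with a pseudocount of 0.1.

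**Figure D2:**
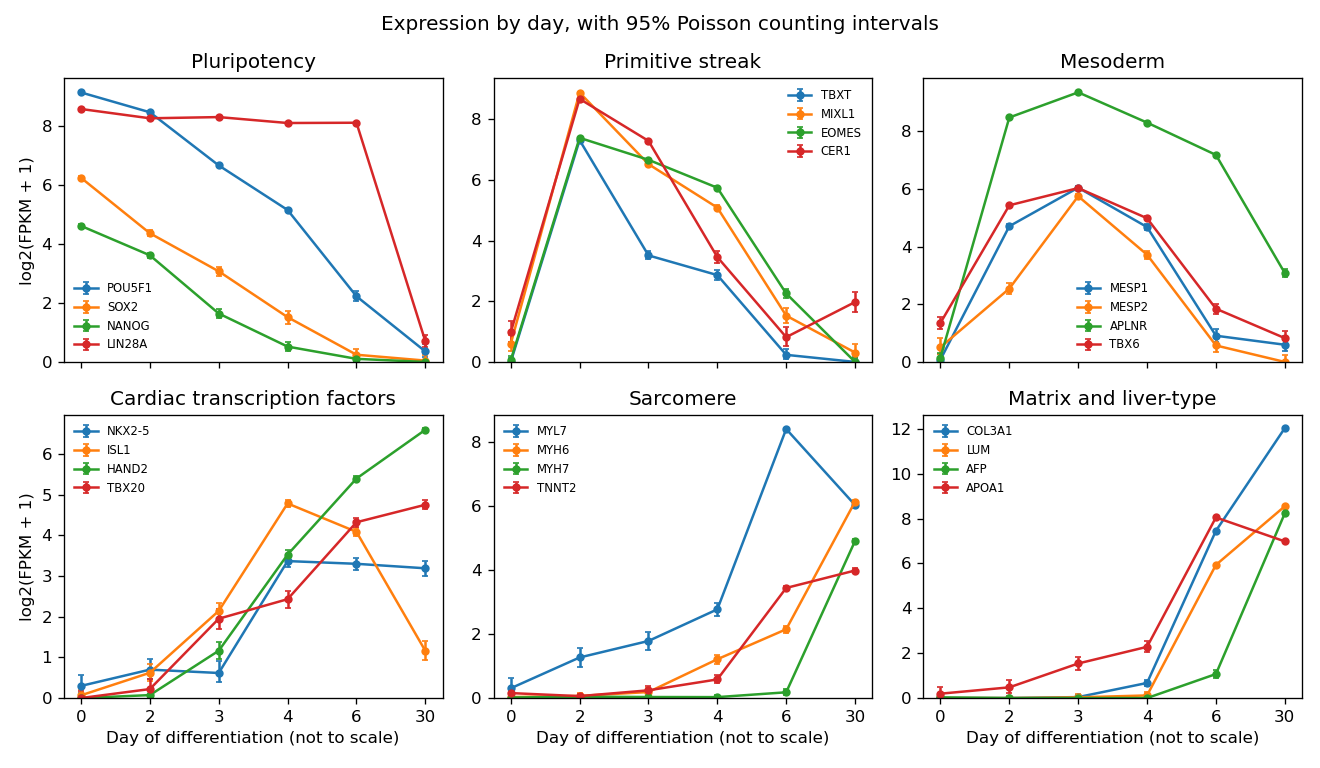
Points give log2(FPKM + 1) of named genes (vertical axis) in the 1 library of each day (horizontal axis, not to scale), with 95% Poisson intervals for counting error. MIXL1 is highest at day 2 with 472 FPKM, MESP2 at day 3 with 52.9 FPKM, and MYH6 at day 30 with 69.0 FPKM.

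Between day 4 and day 6, 8 of 15 measured sarcomere genes, 7 of 15 measured matrix genes and 10 of 12 measured endoderm and liver genes rose. The full lists hold 26, 18 and 14 genes. MYL7 (ENSG00000106631, chromosome 7, 44138864 to 44141332, minus strand), the atrial myosin light chain, rose from 5.82 to 336 FPKM (57.7-fold higher, 48.7 to 69.0). TNNT2 (0.497 to 9.83 FPKM, 19.8-fold higher, 15.2 to 26.3), cardiac troponin T, was also higher. COL3A1 (0.595 to 174 FPKM, 293-fold higher, 229 to 380.2), a fibrillar collagen, had the greatest rise. The apolipoprotein APOA1 (3.87 to 264 FPKM, 68.2-fold higher, 55.2 to 85.3) and the thyroid hormone carrier TTR (0 to 66.9 FPKM, at least 844-fold higher) were among the 10 greatest. The streak and mesoderm factors MESP1 (24.7 to 0.879 FPKM, 28.1-fold lower, 20.1 to 40.3) and MIXL1 (33.1 to 1.88 FPKM) fell.

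The sarcomere (8 of 15 higher, 1 lower, median 1.88, percentile 100) list was above other genes. Its members TPM1 (15.8 to 92.2 FPKM), MYL4 (8.70 to 61.9 FPKM) and TNNI1 (1.08 to 15.5 FPKM, 14.4-fold higher, 12.0 to 17.3) rose, and cardiac troponin I, TNNI3 (4.70 to 1.59 FPKM), fell. The cardiac transcription factors (7 of 14 higher, 1 lower, median 0.82, percentile 100) list was above other genes. The factors TBX20 (4.39 to 18.97 FPKM), HAND2 (10.5 to 41.0 FPKM), TBX5 (0.247 to 3.12 FPKM) and MYOCD (0.0428 to 3.18 FPKM) rose. The fibroblast and matrix (7 of 15 higher, 0 lower, median 0.96, percentile 100) list was above other genes. Collagen COL1A2 (17.2 to 108 FPKM) and the proteoglycan LUM (0.0841 to 60.1 FPKM) rose. The endoderm and liver (10 of 12 higher, 2 lower, median 2.14, percentile 100) list was above other genes. The fibrinogen chain FGB (0 to 27.3 FPKM) rose, whereas the early endoderm factors SOX17 (196 to 49.8 FPKM) and FOXA2 (85.4 to 34.1 FPKM) fell.

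The plasminogen activator PLAT (0.172 to 27.6 FPKM), the apelin receptor ligand APELA (1.54 to 51.1 FPKM), HABP2 (0.156 to 22.1 FPKM) and GUCY1A1 (0.176 to 18.8 FPKM) were also among the 10 greatest rises. The greatest falls were led by FGF17 (60.0 to 0.704 FPKM, 85.3-fold lower, 62.5 to 119.6). The axon guidance protein NTN1 (48.6 to 0.961 FPKM), the retinoic acid-degrading enzyme CYP26A1 (68.9 to 2.49 FPKM, 27.7-fold lower, 23.2 to 33.3) and TNS4 (16.7 to 0.155 FPKM) were further cases. STMN2 (22.5 to 0.539 FPKM), ZAP70 (96.3 to 7.32 FPKM) and the FGF pathway inhibitor SPRY4 (88.8 to 6.92 FPKM) fell too. The retinoic acid and HOX (5 of 7 higher, 1 lower, median 1.19, percentile 100) list was above other genes. Its members HOXB1 (1.89 to 29.6 FPKM) and HOXB4 (2.39 to 15.1 FPKM) rose against CYP26A1.

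The cell cycle (1 of 22 higher, 0 lower, median 0.55, percentile 100) and atrial (6 of 9 higher, 2 lower, median 1.61, percentile 100) lists were above other genes. The first heart field (2 of 4 higher, 0 lower, median 1.12, percentile 99.91) and ion channels and calcium handling (4 of 15 higher, 4 lower, median 0.34, percentile 97.52) lists were above other genes. The epicardial (2 of 5 higher, 0 lower, median 0.89, percentile 99.62) and endothelial and endocardial (4 of 13 higher, 5 lower, median 0.35, percentile 99.18) lists were above other genes. The blood (2 of 4 higher, 0 lower, median 0.92, percentile 99.47) list was above other genes. The primitive streak (0 of 13 higher, 10 lower, median -1.65, percentile 0) and early and cardiac mesoderm (2 of 16 higher, 7 lower, median -0.77, percentile 0) lists were below other genes. The pluripotency (0 of 17 higher, 5 lower, median -0.54, percentile 0.21) and WNT targets (0 of 12 higher, 5 lower, median -0.64, percentile 0.02) lists were below other genes. The neuroectoderm and neuron (0 of 3 higher, 2 lower, median -2.23, percentile 0) and hypoxia (0 of 9 higher, 1 lower, median -0.54, percentile 0.665) lists were below other genes. The unfolded protein response (0 of 10 higher, 6 lower, median -1.20, percentile 0) and immediate early (0 of 8 higher, 3 lower, median -0.92, percentile 0) lists were below other genes. The antigen presentation (0 of 8 higher, 2 lower, median -0.59, percentile 0.98) list was below other genes.

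Of 16727 genes, 922 were higher at day 6 and 1123 lower (3459 and 2693 under TPM scaling, 1595 and 1785 with a pseudocount of 0.1 and 425 and 489 at an FPKM minimum of 5), so that 45.1% of the changed genes were higher, against 56.2% under TPM scaling, 53.3% with mitochondrial and top 20 genes left out of the scaling and 50.7% of protein-coding genes alone. The endothelial list was below other genes at an FPKM minimum of 5 (median -1.31, percentile 0) and changed sign as a mean, the blood list was below without the minimum (percentile 1.57), and the pluripotency, first heart field, ion channel and neuroectoderm calls were lost under at least 1 alternative. The ion channel call was lost under most alternatives, and the mean of its members lay at percentile 64.5.

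Day 30 against day 6 spans the longest interval between consecutive libraries and had the most changed genes of the 5 steps. MYH6 (ENSG00000197616, chromosome 14, 23381990 to 23408277, minus strand), the alpha cardiac myosin heavy chain, rose from 3.43 to 69.0 FPKM (20.1-fold higher, 18.1 to 22.4). MYH7 (0.133 to 28.9 FPKM, 217-fold higher, 129 to 398), the beta chain, and PLN (0.289 to 60.1 FPKM, 208-fold higher, 113 to 434), the calcium pump regulator phospholamban, rose as well. Collagen COL3A1 (174 to 4173 FPKM, 24.0-fold higher, 23.6 to 24.3) took 2.35% of all reads at day 30. The FPKM denominators were 0.826 times the read total at day 30 and 1.12 times at day 6. With read totals instead, every fold rise in this comparison would be smaller and every fold fall greater. The proliferation marker MKI67 (27.2 to 5.35 FPKM, 5.10-fold lower, 4.74 to 5.48) fell. The RNA-binding protein LIN28A (275 to 0.626 FPKM, 439-fold lower, 309 to 647) had the greatest fall.

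The sarcomere (13 of 24 higher, 5 lower, median 1.34, percentile 100) list was above other genes. Its members MYBPC3 (0.0405 to 17.7 FPKM), CSRP3 (0 to 17.0 FPKM) and MYL3 (1.53 to 24.998 FPKM) rose. The members MYL7 (336 to 64.0 FPKM, 5.25-fold lower, 4.93 to 5.58), MYL4 (61.9 to 20.2 FPKM) and NEBL (14.3 to 3.71 FPKM) fell. The 26 sarcomere genes together took 0.326% of reads at day 6 and 0.208% at day 30. The 18 matrix genes took 1.79% and 5.72%. The ventricular (5 of 7 higher, 0 lower, median 2.35, percentile 100) and cardiac hormones and receptors (7 of 7 higher, 0 lower, median 1.79, percentile 99.91) lists were above other genes. The LIM protein FHL2 (0.890 to 26.9 FPKM), the natriuretic peptide NPPB (2.00 to 28.3 FPKM, 14.2-fold higher, 9.30 to 22.5) and the angiotensin receptor AGTR1 (0.0166 to 16.4 FPKM) rose. The cardiac transcription factors (2 of 16 higher, 3 lower, median -0.01, percentile 24.87) list was not called. Among them HAND2 (41.0 to 95.4 FPKM) rose, and ISL1 (16.0 to 1.24 FPKM) and HAND1 (277 to 37.7 FPKM) fell. The atrial (5 of 11 higher, 3 lower, median -0.63, percentile 3.03) and pacemaker (0 of 5 higher, 2 lower, median -0.62, percentile 7.935) lists were not called. The ion channels and calcium handling (5 of 17 higher, 2 lower, median 0.45, percentile 86.95) list was not called. The first heart field (0 of 4 higher, 2 lower, median -1.19, percentile 1.21) list was below other genes.

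The fibroblast and matrix (13 of 18 higher, 0 lower, median 1.96, percentile 100) and smooth muscle and pericyte (8 of 10 higher, 1 lower, median 1.86, percentile 99.99) lists were above other genes. The matrix genes POSTN (0.254 to 132 FPKM) and DCN (0.0630 to 39.7 FPKM) rose. The intermediate filament DES (0.751 to 86.6 FPKM) and the receptor PDGFRB (15.2 to 182 FPKM) rose, and RGS5 (94.2 to 14.0 FPKM) fell. The macrophage (8 of 9 higher, 0 lower, median 1.15, percentile 98.1) list was above other genes. Its members CD14 (0 to 4.98 FPKM) and C1QC (0 to 1.94 FPKM) rose, and none of the list passed 4.98 FPKM. The endoderm and liver (6 of 14 higher, 6 lower, median -0.78, percentile 0.01) list was below other genes. The early endoderm factor SOX17 (49.8 to 2.38 FPKM) fell. Alpha-fetoprotein, AFP (1.10 to 299 FPKM, 272-fold higher, 212 to 355), and SERPINA1 (0.106 to 114 FPKM) rose. The fatty acid oxidation (10 of 19 higher, 1 lower, median 1.23, percentile 99.99) list was above other genes. The kinase PDK4 (0.115 to 106 FPKM, 919.8-fold higher, 484 to 2013) and ACSL1 (0.828 to 46.9 FPKM) rose against ACADM (8.60 to 2.83 FPKM).

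The immediate early (8 of 9 higher, 0 lower, median 4.19, percentile 100) and unfolded protein response (8 of 10 higher, 0 lower, median 1.98, percentile 99.99) lists were above other genes. The hypoxia (8 of 11 higher, 0 lower, median 1.51, percentile 99.93) and p53 response (6 of 10 higher, 0 lower, median 1.17, percentile 99.58) lists were above other genes. The antigen presentation (6 of 8 higher, 0 lower, median 2.65, percentile 100) list was above other genes. Examples were DUSP1 (4.04 to 209 FPKM), ATF3 (1.56 to 66.3 FPKM), NDRG1 (2.82 to 141 FPKM), CDKN1A (9.12 to 119 FPKM) and B2M (12.0 to 154 FPKM). The mesenchymal (5 of 10 higher, 0 lower, median 1.33, percentile 99.65) and NOTCH targets (4 of 6 higher, 0 lower, median 1.32, percentile 98.84) lists were above other genes. The skeletal muscle (4 of 4 higher, 0 lower, median 2.43, percentile 99.98) and neural crest (3 of 3 higher, 0 lower, median 2.40, percentile 99.86) lists were above other genes. Their full lists hold 12 and 9 genes, of which 8 and 6 were under the FPKM minimum on both days. The skeletal muscle list shares CKM with the muscle energy list, and these 2 calls do not identify a cell type. The neuroectoderm and neuron (2 of 3 higher, 1 lower, median 2.84, percentile 99.89) and cartilage (3 of 5 higher, 2 lower, median 1.71, percentile 99.31) lists were above other genes. Their full lists hold 14 and 8 genes. The replication-dependent histone (2 of 3 higher, 0 lower, median 2.39, percentile 99.9) list was above other genes. Its full list holds 9 genes, and without the FPKM minimum its median was 0.246 at percentile 90.05. RNA was purified with poly-T beads, so transcripts without a poly-A tail may be missed. The 3 measured genes therefore do not describe the class.

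The cell cycle (0 of 22 higher, 21 lower, median -1.87, percentile 0) and mitochondrial genome (0 of 13 higher, 5 lower, median -0.80, percentile 0) lists were below other genes. The helicase subunit MCM4 (28.5 to 3.29 FPKM, 8.68-fold lower, 7.69 to 9.84) is an example of the former. The pluripotency (0 of 14 higher, 14 lower, median -2.79, percentile 0) and primitive streak (2 of 11 higher, 8 lower, median -1.22, percentile 0.08) lists were below other genes. The early and cardiac mesoderm (2 of 13 higher, 6 lower, median -0.42, percentile 1.485) and WNT targets (0 of 11 higher, 7 lower, median -1.14, percentile 0.14) lists were below other genes. The BMP targets (0 of 9 higher, 7 lower, median -1.78, percentile 0) and blood (1 of 5 higher, 3 lower, median -1.82, percentile 0.16) lists were below other genes.

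The greatest rises included the metallothioneins MT2A (0.445 to 1102 FPKM, 2474-fold higher, 1345 to 5159.6) and MT1E (0 to 117 FPKM). The protease inhibitors TFPI2 (2.07 to 491 FPKM) and SLPI (0.388 to 216 FPKM) were others. The growth factor AREG (0 to 147 FPKM), the transcription factor CEBPD (5.34 to 903 FPKM, 169-fold higher, 147 to 195) and the prostaglandin synthase PTGS2 (0.0549 to 139.7 FPKM) rose. AFP and the chemokine CXCL8 (0.0254 to 123 FPKM) were also among the 10 greatest. Beside LIN28A, HAPLN1 (76.9 to 0.524 FPKM), APELA (51.1 to 0.0786 FPKM), TMEM88 (464 to 10.1 FPKM) and CFC1 (51.3 to 0.436 FPKM) had the greatest falls. PRTG (141 to 2.98 FPKM), ALPL (62.9 to 1.13 FPKM), HOXB1 (29.6 to 0.0327 FPKM), CCKBR (42.2 to 0.518 FPKM) and SFRP5 (56.3 to 1.06 FPKM) followed.

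Of 18023 genes, 3776 were higher at day 30 and 2761 lower, and the 57.8% share of higher genes became 43.3% under TPM scaling (5512 and 7209 genes), 62.4% at an FPKM minimum of 5 (2294 and 1384), 39.7% with mitochondrial and top 20 genes left out of the scaling, and 37.4% with scaling by read totals, a setting chosen after seeing the data. The endoderm and liver median changed sign as a mean or with members of 1 list only, and the mesoderm, neuroectoderm, neural crest, blood, macrophage, cartilage, NOTCH target and histone calls were lost under at least 1 alternative.

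Across the whole course, from day 0 to day 30, every measured pluripotency gene fell. POU5F1 (ENSG00000204531, chromosome 6, 31164337 to 31180731, minus strand) went from 561 to 0.280 FPKM (2008-fold lower, 1092 to 4189). L1TD1 (288 to 0.273 FPKM, 1052-fold lower, 615 to 1976), SOX2 (74.7 to 0.0322 FPKM) and LIN28A (380.2 to 0.626 FPKM) fell with it. The pluripotency (0 of 20 higher, 20 lower, median -5.00, percentile 0) list was below other genes. The sarcomere (22 of 24 higher, 0 lower, median 2.62, percentile 100) and fibroblast and matrix (17 of 18 higher, 1 lower, median 5.12, percentile 100) lists were above other genes. Troponin T, TNNT2 (0.114 to 14.8 FPKM, 130.0-fold higher, 74.1 to 252), and the actinin ACTN2 (1.46 to 18.3 FPKM) rose. COL3A1 (0 to 4173 FPKM, at least 137660.0-fold higher) was first among all protein-coding genes, and the 1 matrix gene to fall was THY1 (82.4 to 3.51 FPKM).

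The NOTCH-ligand-like membrane protein DLK1 (0.0777 to 1900.4 FPKM, 24445-fold higher, 11231 to 66613) and the deiodinase DIO3 (1.80 to 1106 FPKM, 614-fold higher, 472 to 816) were next among the rises. CEBPD (1.33 to 903 FPKM), the small matrix proteoglycans LUM (0 to 373 FPKM) and FMOD (0.142 to 381 FPKM), and AFP (0.0211 to 299 FPKM) followed. The protease PAPPA (0.107 to 261 FPKM), SLPI (0 to 216 FPKM) and TGFBI (1.37 to 401 FPKM) complete the 10. DPPA4 (333 to 1.81 FPKM), TDGF1 (150.5 to 0.781 FPKM), ZIC2 (73.4 to 0 FPKM) and PTPRZ1 (72.7 to 0.00816 FPKM) were among the greatest falls. ZSCAN10 (77.2 to 0.0976 FPKM) and NANOGP8 (61.9 to 0 FPKM) fell too, the latter a retrogene copy of NANOG whose reads can come from NANOG.

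The cardiac transcription factors (12 of 14 higher, 0 lower, median 3.50, percentile 100) and cardiac hormones and receptors (6 of 7 higher, 0 lower, median 3.52, percentile 100) lists were above other genes. The atrial (9 of 9 higher, 0 lower, median 4.41, percentile 100) and ventricular (4 of 7 higher, 0 lower, median 2.35, percentile 99.91) lists were above other genes. The first heart field (3 of 4 higher, 1 lower, median 2.10, percentile 99.51) list was above other genes. The factors HAND2 (0 to 95.4 FPKM) and TBX20 (0 to 25.9 FPKM) rose. The pacemaker channel HCN4 (17.9 to 1.46 FPKM) fell against the first heart field list. The ion channels and calcium handling (6 of 16 higher, 2 lower, median 0.68, percentile 92.33) and pacemaker (3 of 6 higher, 2 lower, median 0.63, percentile 73.42) lists were not called. The endoderm and liver (13 of 14 higher, 0 lower, median 4.26, percentile 100) and epicardial (7 of 9 higher, 0 lower, median 2.23, percentile 100) lists were above other genes. The endothelial and endocardial (9 of 12 higher, 1 lower, median 1.45, percentile 99.87) and smooth muscle and pericyte (9 of 10 higher, 0 lower, median 1.78, percentile 99.98) lists were above other genes. The epicardial factor WT1 (0 to 14.8 FPKM) rose. The macrophage (7 of 9 higher, 0 lower, median 1.41, percentile 99.62) and mesenchymal (9 of 10 higher, 0 lower, median 3.40, percentile 100) lists were above other genes. The skeletal muscle (3 of 5 higher, 1 lower, median 1.44, percentile 98.29) list was above other genes.

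The neuroectoderm and neuron (2 of 7 higher, 5 lower, median -1.29, percentile 0.415) list was below other genes. The epithelial (3 of 11 higher, 4 lower, median -0.47, percentile 8.62) and cartilage (3 of 5 higher, 1 lower, median 1.11, percentile 92.28) lists were not called. The neural crest (2 of 5 higher, 1 lower, median -0.00064, percentile 41.23) list was not called. Blood had too few measured genes for a percentile (1 of 2 higher, 0 lower, median 1.28). The fatty acid oxidation (9 of 19 higher, 1 lower, median 0.998, percentile 99.33) and muscle energy (3 of 4 higher, 0 lower, median 1.55, percentile 98.02) lists were above other genes. The glycolysis (1 of 17 higher, 7 lower, median -0.86, percentile 0.13) and nuclear oxidative phosphorylation (1 of 21 higher, 3 lower, median -0.57, percentile 1.46) lists were below other genes. The housekeeping (2 of 12 higher, 5 lower, median -0.83, percentile 0.93) and cell cycle (0 of 22 higher, 22 lower, median -2.47, percentile 0) lists were below other genes. The mitochondrial genome (0 of 13 higher, 13 lower, median -1.94, percentile 0) list was below other genes. All mitochondrially encoded genes together took 7.51% of reads at day 0 and 1.91% at day 30.

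The early and cardiac mesoderm (9 of 13 higher, 1 lower, median 2.62, percentile 100) and retinoic acid and HOX (6 of 7 higher, 1 lower, median 2.46, percentile 99.99) lists were above other genes. The BMP targets (6 of 9 higher, 0 lower, median 1.47, percentile 99.3) and NOTCH targets (4 of 6 higher, 0 lower, median 1.72, percentile 99.22) lists were above other genes. The unfolded protein response (7 of 10 higher, 1 lower, median 1.56, percentile 99.79) and immediate early (6 of 9 higher, 2 lower, median 1.46, percentile 99.43) lists were above other genes. The antigen presentation (6 of 10 higher, 0 lower, median 1.33, percentile 99.45) and replication-dependent histone (2 of 3 higher, 0 lower, median 2.25, percentile 99.49) lists were above other genes. The full histone list holds 9 genes, and without the FPKM minimum its median was 0.246 at percentile 87.3.

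In all 4635 of 17874 genes were higher at day 30 and 3406 lower, against 8138 and 5538 under TPM scaling and 2730 and 2115 at an FPKM minimum of 5, but 3836 were higher and 4042 lower with mitochondrial and top 20 genes left out of the scaling, and 3729 and 4039 with read totals, a setting chosen after seeing the data. The first heart field, endothelial, neuroectoderm, skeletal muscle, macrophage, oxidative phosphorylation, muscle energy, immediate early, antigen presentation, histone and housekeeping calls were lost under at least 1 alternative. The skeletal muscle call was lost under most alternatives, with a median of 0.36 at percentile 52.68 for members of 1 list only and of 0.68 at percentile 68.27 under TPM scaling.

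**Figure D3:**
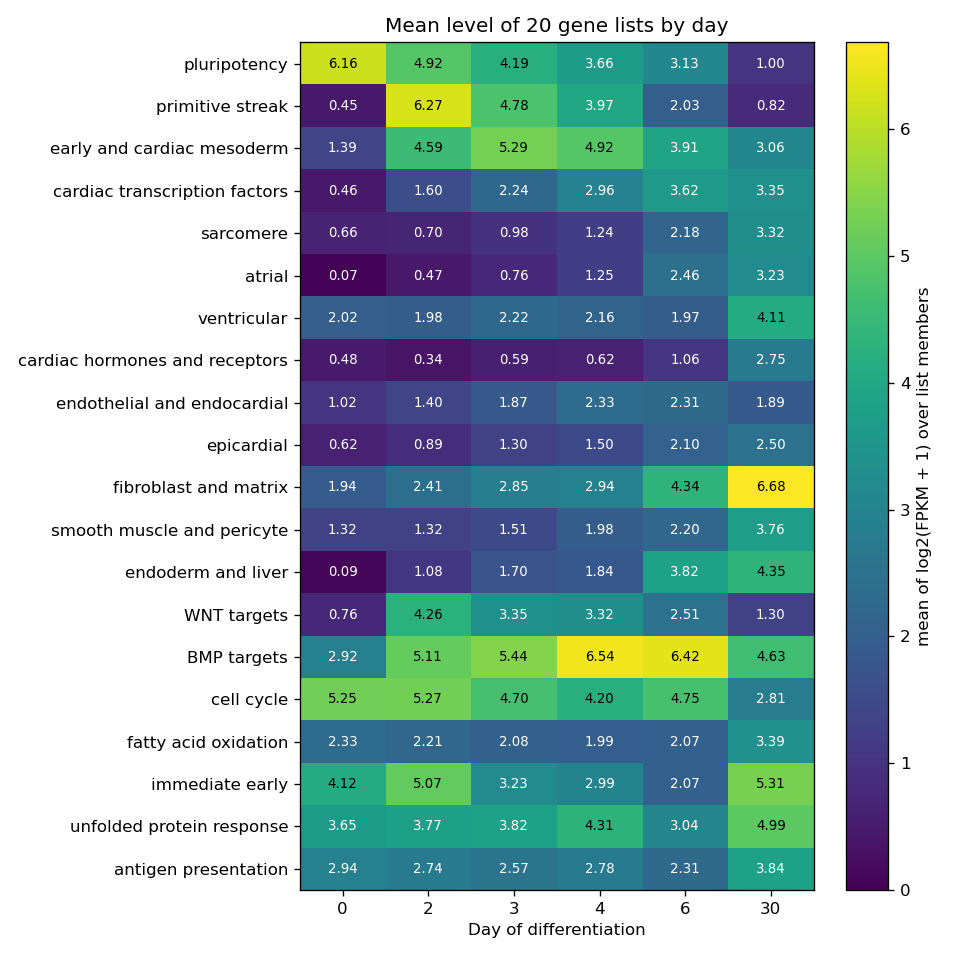
Each cell gives the mean log2(FPKM + 1) of the members of 1 of 20 gene lists (vertical axis) in the library of each day (horizontal axis). The primitive streak list is highest at day 2 with 6.27, BMP targets at day 4 with 6.54, and the fibroblast and matrix list at day 30 with 6.68.

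Paired sarcomere genes were compared within each library. The share of MYH7 in MYH7 plus MYH6 was 1.56% at day 4, 3.73% at day 6 and 29.5% at day 30 (exact binomial 95% interval 28.5 to 30.6). The day 4 share rests on 2 reads of MYH7, and its interval (0.189 to 5.50) overlaps that of day 6 (2.06 to 6.18). MYL2, the ventricular myosin light chain, had 0 reads from day 2 to day 6, which at day 6 allows a share of up to 0.0466%. It made up 6.02% of MYL2 plus MYL7 at day 30 (interval 4.72 to 7.55). The share of TNNI3 in TNNI3 plus TNNI1 was 93.7% at day 0 (interval 90.0 to 96.3), 9.33% at day 6 (7.19 to 11.8) and 13.5% at day 30 (9.27 to 18.7). The intervals of day 6 and day 30 overlap. By reads not divided by gene length it was 80.2%, 2.71% and 4.05% on these days. TNNI3 had 2.61 FPKM at day 0, and TNNI1 reached 15.5 FPKM at day 6.

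Of 20481 genes with an FPKM of at least 1 on any day, 14210 passed the rule between their lowest and highest day. Day 30 held the highest level of 5034 of them and day 0 of 3008. Day 2 held that of 1538, day 3 of 1226, day 4 of 1564 and day 6 of 1840. Under TPM scaling day 3 held 3497, day 4 held 2855 and day 6 held 5565, and day 6 held 2795 with scaling by read totals, a setting chosen after seeing the data. At an FPKM minimum of 5 day 6 held 830 and day 30 held 2946. Transient genes, past the rule above both day 0 and day 30, numbered 2159. The highest of 6 single libraries was taken for each gene, so counting noise can raise these counts. The transient count was not repeated under the alternatives. Pearson's r across genes was 0.902 between days 0 and 2, 0.932 between days 2 and 3, and 0.953 between days 3 and 4. It was 0.920 between days 4 and 6, 0.753 between days 6 and 30, and 0.676 between days 0 and 30. Spearman's rho was 0.934 for days 3 and 4 and 0.637 for days 0 and 30. These coefficients use log2(FPKM + 1), and genes are not independent replicates.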

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

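Scaling by recovered read totals and the GC bins were chosen after seeing the data. Genes with the greatest rise or fall were chosen for the size of their change, so most alternatives could not end their calls, and ATP8B4 at day 4 was left out by the FPKM minimum of 5. Of 141 called list medians, 97 kept their call under every alternative that gave a value and 44 lost it under at least 1. Not every alternative gave a value for all of them. At an FPKM minimum of 5, 102 kept the call, 10 lost it and 1 changed sign. With members of 1 list only, these numbers were 114, 8 and 1. Median-of-ratios scaling, which kept all 141, nearly repeats the deposited scaling and so could hardly end a call. A scaling acts alike on all genes of a library, so it can move these percentiles only through the pseudocount and the minimum. Leaving out the FPKM minimum changes no count of higher or lower genes by construction, because a rule of 1 with a pseudocount of 1 already needs an FPKM of at least 1. No paired analysis was possible because each time point was 1 library, and no sample had more than 1 column, so runs were not compared. TPM scaling moved the median over the genes tested to 0.23 at day 3 against day 2, -0.12 at day 4 against day 3, 0.18 at day 6 against day 4, -0.22 at day 30 against day 6 and 0.25 at day 30 against day 0, where the deposited values gave -0.02, -0.00408, -0.00693, 0.08 and 0.13. Read totals moved it to -0.33 and -0.11 in the last 2, and leaving out mitochondrial and top 20 genes to -0.28 and -0.10, with 0.11 at day 6 against day 4. Depth limits genes of low level or short length. Of the 15457 genes with an FPKM of at least 1 at day 30, 1988 rested on fewer than 20 reads.

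A pseudocount of 0.1, which by construction shrinks the changes of low genes less, gave 2130 higher and 2092 lower for day 2 against day 0, 2061 higher and 1378 lower for day 3 against day 2, 1260 higher and 1101 lower for day 4 against day 3, 1595 higher and 1785 lower for day 6 against day 4. An FPKM minimum of 5, with fewer genes tested, gave 698 higher and 621 lower for day 2 against day 0, 572 higher and 367 lower for day 3 against day 2, 209 higher and 233 lower for day 4 against day 3, 425 higher and 489 lower for day 6 against day 4, 2294 higher and 1384 lower for day 30 against day 6, 2730 higher and 2115 lower for day 30 against day 0. TPM scaling, which changes both the scaling between libraries and the level at which the pseudocount and minimum act, gave 3625 higher and 2781 lower for day 2 against day 0, 4143 higher and 1959 lower for day 3 against day 2, 2240 higher and 2369 lower for day 4 against day 3, 3459 higher and 2693 lower for day 6 against day 4, 7209 lower for day 30 against day 6, 8138 higher and 5538 lower for day 30 against day 0. Protein-coding genes alone, with fewer genes tested, gave 784 higher and 639 lower for day 2 against day 0, 516 higher and 375 lower for day 3 against day 2, 223 higher and 193 lower for day 4 against day 3, 531 higher and 516 lower for day 6 against day 4, 1736 lower for day 30 against day 6. The rule of 2 on the log2 scale, stricter by construction, gave 302 higher and 133 lower for day 2 against day 0, 144 higher and 69 lower for day 3 against day 2, 63 higher and 50 lower for day 4 against day 3, 153 higher and 179 lower for day 6 against day 4, 1107 higher and 485 lower for day 30 against day 6, 1513 higher and 856 lower for day 30 against day 0. The demand that the counting interval excludes 1 gave 403 higher and 366 lower for day 4 against day 3. Scaling by recovered read totals gave 4300 lower for day 30 against day 6. The cause was not tested. The number of genes highest on a day became under the FPKM minimum of 5 1897 for day 0, 929 for day 2, 565 for day 3, 657 for day 4, 830 for day 6, 2946 for day 30. The number of genes highest on a day became under TPM scaling 3497 for day 3, 2855 for day 4, 5565 for day 6. The number of genes highest on a day became under scaling by read totals 2795 for day 6. Without division by gene length the TNNI3 share was 80.2% at day 0, 87.3% at day 2, 75.1% at day 3, 54.1% at day 4, 2.71% at day 6, 4.05% at day 30, and the MYH7 share 28.2% at day 30. Over 9726 protein-coding genes with an FPKM of at least 5, Pearson's r became 0.450 for day 0 and day 30 and 0.580 for day 6 and day 30. List medians that changed sign were -1.31 for endothelial and endocardial genes at day 6 against day 4 under FPKM minimum 5, -0.16 for endothelial and endocardial genes at day 6 against day 4 under mean of members, 0.53 for endoderm and liver genes at day 30 against day 6 under mean of members, 0.20 for endoderm and liver genes at day 30 against day 6 under members of 1 list only, -0.0696 for neuroectoderm and neuron genes at day 3 against day 2 under no filter, -0.0287 for neuroectoderm and neuron genes at day 3 against day 2 under TPM scaling, -0.000902 for blood genes at day 6 against day 4 under no filter, and the cause was not tested.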

Other observations

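The tests on long intergenic noncoding genes, the MEG3 limit, the ratio of ALB to AFP, the APOA1 ratio and the endoderm factors were chosen only after the result was seen. The genes named here were also chosen after their values were seen. At day 30 the chemokines CXCL8 and CXCL1 had 123 and 88.3 FPKM, where day 6 had 1 read of CXCL8 and 0.134 FPKM of CXCL1. The cytokines IL6 and IL1B rose from 0 reads at day 6 to 36.8 and 18.7 FPKM. The NF-kB inhibitors TNFAIP3 (7.04 to 182 FPKM, 25.8-fold higher, 23.8 to 28.0) and NFKBIA (15.2 to 181 FPKM, 11.9-fold higher, 10.96 to 13.0), the superoxide dismutase SOD2 (2.17 to 66.0 FPKM) and the chemokine CCL2 (0.874 to 40.2 FPKM) rose too. The lipid droplet protein PLIN2 (11.1 to 1248 FPKM, 113-fold higher, 106 to 120.2) rose as well.

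The metallothionein MT2A went from 23.6 FPKM at day 0 to 0.0487 at day 4 and 1102 at day 30, and MT1G from 67.9 at day 0 to 0 reads at day 6 and 82.9 at day 30. TMEM88, which encodes an inhibitor of WNT signalling, had 0.629 FPKM at day 0, 464 at day 6 and 10.1 at day 30. The growth inhibitor CDKN1C rose from 10.1 FPKM at day 0 to 474 at day 30.

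Genes of chromosome 19 were higher and genes of chromosome 4 lower against day 0 in every later library, with medians of 0.27 and -0.24 on the log2 scale at day 2. An extra copy of chromosome 19 is argued against by the largest median of its genes after correction for GC content, 0.0532, which lay under the bound of 0.29 set in advance, an argument that rests on the correction since the uncorrected median reached 0.30 at day 3. The median GC content of the transcripts was 42.3% on chromosome 4 and 59.1% on chromosome 19, and GC content may account for the gap. After correction 21.7%, 18.7%, 16.0% and 1.14% of its size were left at the 4 days from day 2 to day 6, with intervals up to at most 34.7%, while at day 30 42.2% was left with the sign turned and an interval up to 92.7%, so GC content cannot be told apart from other causes at day 30, a reading by size taken after the signed remainder had been seen. Unlike the other intervals, these come from redrawing the genes of each chromosome at random. They take genes as independent and hold the uncorrected gap fixed. A bias of the day 0 library also stays open, since rho of change and GC content across genes, which are not independent replicates, was 0.436 for day 2 against day 0 and 0.0353 for day 30 against day 6, and regulation linked to GC content would give the same values.

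At day 30 the imprinted genes DLK1, DIO3, RTL1 and IGF2 had 1900.4, 1106, 10.1 and 163 FPKM, while the noncoding genes of the same regions, MEG3 and H19, had 0.0383 and 0.838. Whether a general loss of long noncoding RNAs in this library took part cannot be decided from a count of genes. Such a count does not show that MEG3 and H19 fell with the others. Long intergenic noncoding genes with an FPKM of at least 10 numbered 19 at day 30, below the limit set from day 0. They numbered 50, 38, 40, 47 and 36 at days 0, 2, 3, 4 and 6, so the fall is larger against day 0 than against day 6. The noncoding NEAT1 nevertheless rose from 4.27 to 50.8 FPKM between days 6 and 30. Changed imprinting of both regions cannot be told apart from other causes, because the table holds no reads that separate the parental copies, and the upper limit of MEG3 was 0.0686 FPKM.

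In the endoderm and liver list 10 of 12 measured genes were higher at day 6 than at day 4, and 13 of 14 were higher at day 30 than at day 0, while 6 were higher and 6 lower at day 30 than at day 6. RNA of adult liver is argued against by the ratio of ALB to AFP at day 30, which was 0.0487 (95% interval 0.0448 to 0.0528), where adult liver has more ALB than AFP. Reads leaking between these libraries in 1 fixed proportion are argued against by APOA1, whose level at day 30 was 0.475 times that at day 6 (interval 0.453 to 0.499), while AFP was 272-fold higher, 212 to 355. Endoderm cells within the organoids may be the source. The rule against day 0 was passed at day 4 by 5 of 5 endoderm transcription factors of the list. Among them SOX17 had 196 and FOXA2 had 85.4 FPKM at day 4. FOXA2 is also in the primitive streak list and SOX17 in the endothelial list, so the count is not specific to endoderm. Whether the factors rose before the liver-type genes was not checked. An endoderm source remains a hypothesis, since bulk RNA does not show which cells hold the transcripts.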
